A study of Drosophila melanogaster with 46 samples.

How the data were processed

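Whole virgin females of 12 inbred Drosophila melanogaster lines were measured on 46 Affymetrix arrays at 2 ages and after 2 kinds of injection. The deposited values are log2 GCRMA signals, which the authors made with GCRMA 2.18.0 in R 2.10.0 per the labels. They ran from a floor of 2.16, shared by 39.6% of values, to 15.5, and no pair of arrays was identical. Probe-level files were not used here. Array signal has no counting depth, and the number of arrays limits the precision.

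The 183 control probe sets were left out of 18952. A probe set was kept when at least 10 arrays, the size of the smallest group, had a log2 value above 4, which kept 8741 of 18769 (46.6%). Of those kept, 7770 carried 1 gene symbol, 229 several and 742 none, and 7360 genes were represented. Symbols were checked against a current gene table: 13543 of the 13646 probe sets with 1 gene kept their symbol, 103 had no match and 0 were updated.

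The groups, the comparisons, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. One linear model with the 4 groups of age and injection and with inbred line as a fixed block was fitted to each probe set with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (31 residual degrees of freedom). Its contrasts were infection at 1 week, infection at 4 weeks, age in sham-injected flies, age in infected flies, and the difference between the infection effects at both ages. Moderated F-tests covered line, line by age and line by infection. For line by age the injections of a line at an age served as its replicates, and for line by infection its ages did. Adjusted p are Benjamini-Hochberg values over all kept probe sets of a comparison, with a threshold of 0.05. Line numbers pair the arrays: after removal of group means, arrays of the same line correlated with mean r 0.409 and arrays of different lines with -0.047.

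Of 35 gene lists, covering immune defence, metabolism, detoxification, stress, tissues and cell types, 32 had at least 3 measured genes and were tested, with 1 probe set per gene. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, with adjusted p over the lists of a contrast; fry was also run. For each list the genes past the threshold over all probe sets were counted, and those past it when adjusted over the list alone. For each contrast the named genes were those with 1 gene symbol, past the threshold and with the same sign in at least 80 percent of lines: the 10 largest rises and the 10 largest falls, 1 probe set per gene, the one with the highest mean. Every measured antimicrobial peptide gene could be named, and from each other list the 3 largest changes past the threshold, or else the 2 genes with the highest mean. For each F-test the 10 genes with the largest F could be named.

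The mean log2 signal over the 6 antimicrobial peptide genes was compared per line with two-sided sign-flip permutation tests. The correlation between ages over lines and the spread between lines were tested by permutation, and adjusted p were taken over these 4 tests. The lines' class of bacterial clearance is not among the labels used, so it was not analysed here.

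The nearest line of each array was found on residuals from group means, over the 200 probe sets with the largest line F when that array was left out, by correlation with the mean of each line's other arrays; other numbers of probe sets were also tried. Its position between the means of 2 lines (0 for its own line, 1 for the other) was the median over probe sets whose line means differ by over 2 log2 units and whose arrays do not overlap. The 3' minus 5' signal was the mean difference between 3' and 5' control probe sets of 3 housekeeping genes.

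Alternatives planned at the start were no filter, a filter at log2 6 (8012 probe sets), quantile normalization, an intensity trend, array weights, array set as an added block, array set 1 alone, only the 10 lines with all 4 arrays, 1 probe set per gene, no line block, line as a random block, a median over the peptides and leaving out each line. Chosen after seeing the data were fits without the array labelled line 14, 1 week, sham, without the 4 arrays nearest another line, with the 3' minus 5' signal as a covariate, and array weights by the gene-by-gene method, added because the default method stopped before it converged. A fit with the covariate and without the 4 arrays together was also tried and is not reported.

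The analysis was tested on simulated data with known changes in 100 probe sets of each size. The changed probe sets were drawn from those with a mean log2 signal above 6. Changes of 1 log2 unit were recovered for 87, 85, 86 and 84 of 100 in the contrasts of infection at 1 week, infection at 4 weeks, age in sham and age in infected flies, and for 72 of 100 in the interaction. In the F-tests of line, line by age and line by infection, random line effects with an SD of 1 log2 unit were recovered for 97, 68 and 73 of 100. Between 6 and 16 of 8541 unchanged probe sets were called. Simulated residuals were independent between probe sets and arrays, so these counts do not cover real arrays that depart from their group over many probe sets. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.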

Results

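RNA of whole virgin female Drosophila melanogaster from 12 inbred lines, founded from flies of a North Carolina population, was measured on 46 Affymetrix Drosophila arrays, 1 array for each pool of 8 to 15 flies. Flies were 1 or 4 weeks old and were injected with sterile Ringer's solution (sham) or with Escherichia coli, and they were frozen 6 h later. There were 12 sham arrays and 10 infected arrays at 1 week, and 12 sham and 12 infected arrays at 4 weeks. Lines 18 and 20 had no infected array at 1 week. Values are log2 signals, the replicate is the pool of an inbred line, and 8741 of 18769 probe sets stood above the filter on low values. The number of arrays limits the precision. The 3' minus 5' signal of 3 housekeeping genes, a sign of RNA integrity or labelling, averaged 4.73 ± 4.05 log2 units (SD, n = 12) in 1-week sham and 5.04 ± 3.57 (n = 10) in 1-week infected arrays. At 4 weeks it averaged 4.96 ± 3.32 (n = 12) in sham and 5.59 ± 3.91 (n = 12) in infected arrays. It was over 7 in 4, 3, 5 and 6 arrays of these groups, in that order. With group and line in the model, 3191 of 8741 probe sets were associated with this signal (limma, adjusted p under 0.05). Of these, 2111 were higher and 1080 lower where it was larger. Arrays carry numbers in 3 separate runs, which held 33, 7 and 6 arrays and are called array sets here.

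Genes whose level marks a line placed 42 of the 46 arrays nearest to the other arrays of their own line. The array labelled line 14, 1 week, sham had the pattern of line 4 (r = 0.882 with line 4 and r = 0.134 with line 14, over 200 probe sets). Its immune peptide genes stood high for a sham array, with CecB at log2 12.28 against 2.44 to 8.33 in the other 1-week sham arrays, and Def at 14.05 against 2.54 to 10.67. AttD stood at 2.16 in it, and at 2.16 to 2.22 in the line 4 arrays. Also nearest another line were the 4-week infected arrays labelled line 12 (nearest line 1, r = 0.868 against 0.770 with its own), line 17 (nearest line 18, 0.786 against 0.381) and line 18 (nearest line 17, 0.689 against 0.536). This line 17 array lay at 0.815 of the way to line 18 (77.6% of 459 probe sets nearer line 18), and the 4-week sham array of line 17 at 0.633. The line 18 array lay at 0.294 of the way to line 17. Whether the infected arrays of lines 17 and 18 were exchanged or mixed was not settled. All 46 arrays stayed in their labelled groups in the main comparisons. The array labelled line 14, 1 week, sham is called the line 14 young sham array below. Values without it stand beside the counts for the contrasts and the peptide means, while the changes of most named genes are given with it only. Line 14 raised the 1-week sham means of CecB (4.915, and 4.246 without line 14) and Def (8.068 and 7.525).

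The first comparison asked which genes respond to E. coli in young flies. Genes of antibacterial defence rose with infection at 1 week. AttD (Entrez Gene 42122), an attacin, rose, with a fitted log2 change of 5.85 ± 0.68 (SE, 10 infected and 12 sham arrays; adjusted p = 5.22e-06, limma; higher in 9 of 10 lines with both arrays). Its mean in 1-week sham arrays was 3.35, below the filter value of 4, with 2 of 12 arrays at the floor of 2.16, so no fold is given for it, and the sizes of its changes against these arrays, here and with age, are not exact. CecB (Entrez Gene 43598), a cecropin, rose by log2 4.54 ± 0.72 (adjusted p = 0.000338, 9 of 10 lines) and Def (Entrez Gene 36047), the fly defensin, by 4.41 ± 0.62 (adjusted p = 0.000146, 9 of 10 lines). Several 1-week sham arrays also read CecB below the filter value, the lowest at 2.44, while the line 14 young sham array read 12.28. The sizes of the CecB changes against these arrays, here, with age and in the interaction, are therefore not exact. The gene edin, for a peptide induced by infection, rose by log2 3.62 ± 0.56 (9 of 10 lines). Pu, which encodes GTP cyclohydrolase, rose by 2.03 ± 0.33 (9 of 10 lines), and Diedel, a secreted immune modulator, by 3.24 ± 0.64 (10 of 10 lines).

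Of 6 measured antimicrobial peptide genes, 5 rose with infection at 1 week (6 when adjusted over the list alone). Changes were smaller in the peptides already near the top of the scale in sham flies. DptB rose by log2 0.90 ± 0.14 from a sham mean of 13.28, Mtk by 0.62 ± 0.15 from 14.15, and Drs changed by 0.27 ± 0.07 from 14.41 (adjusted p = 0.0514). The list stood above the other genes (camera adjusted p = 1.97e-34, and adjusted p = 1.99e-06 with an estimated correlation). Mtk missed the threshold without line 1, 3, 4, 6, 8, 12, 13, 17 or 19 (adjusted p = 0.0526 to 0.18), and Drs passed it without line 14 (adjusted p = 0.0066) or line 17 (0.036).

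In the immune lists, 2 of 10 bomanins and other immune-induced peptides rose at 1 week (2 when adjusted over the list alone), namely edin and Listericin (log2 2.12 ± 0.42). Of 8 recognition genes of the PGRP and GNBP families 2 rose (4 rose and 1 fell when adjusted over the list alone), PGRP-SB1 by log2 1.48 ± 0.27. Of 10 melanization genes 2 rose (2 when adjusted over the list alone), among them yellow-f, a dopachrome conversion enzyme, by 1.45 ± 0.27. Of 14 Imd pathway genes 1 rose (1 when adjusted over the list alone), pirk, a negative regulator of the pathway, by 1.96 ± 0.42; it missed the threshold without line 4, 8, 12 or 13 (adjusted p = 0.0517 to 0.0909). Camera called these 4 lists upward (adjusted p = 0.000418, 2.94e-05, 7.62e-05 and 0.00337), with adjusted p = 0.24, 0.105, 0.23 and 0.146 with an estimated correlation.

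Falls at 1 week included that of FASN1. This gene, which encodes fatty acid synthase, fell by 1.10 ± 0.19 on the log2 scale (adjusted p = 0.000963, 10 of 10 lines). Miox, a myo-inositol oxygenase, fell by 1.63 ± 0.31 (adjusted p = 0.0035, 10 of 10 lines) and regucalcin fell by 0.79 ± 0.14 (adjusted p = 0.00144, 10 of 10 lines). Of 22 lipid storage and metabolism genes 1 fell (4 when adjusted over the list alone), and camera called the list downward (adjusted p = 2.97e-13, and adjusted p = 0.0352 with an estimated correlation). Of 7 hemocyte markers 1 fell (4 when adjusted over the list alone), Col4a1, a basement membrane collagen, by log2 -0.55 ± 0.12, with camera adjusted p = 8.39e-06 and adjusted p = 0.0456 with an estimated correlation. Without the line 14 young sham array these adjusted p with an estimated correlation were 0.0647 for lipid genes and 0.0811 for hemocyte markers, and Col4a1 missed the threshold without line 3, 6 or 8 (adjusted p = 0.0526 to 0.0724).

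Across all probe sets, 31 rose and 14 fell with infection at 1 week at an adjusted p under 0.05 (limma, with inbred line as a block). Camera called 13 of 32 lists, of which 3 held with an estimated correlation. The others included gut digestive enzymes and cytochrome P450 genes, both downward (adjusted p = 0.00189 and 1.8e-07), with 0 genes past the threshold in each (0 when adjusted over the list alone) and adjusted p = 0.515 and 0.23 with an estimated correlation. Without the line 14 young sham array 68 rose and 19 fell, and without all of line 14 the total was 85. In array set 1 alone the total was 36 (35 rose and 1 fell), with array set as an added block 41 (29 and 12), and without line as a block 24 (21 and 3). Rises did not outnumber falls with array weights (157 rose and 178 fell; 135 and 151 by the gene-by-gene method), and they were not much more numerous than falls in the 10 lines with all 4 arrays (28 and 27) and without line 18 (32 and 28). Array sets 2 and 3 held too few arrays to be tested alone, here and below.

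At 4 weeks, infection again raised immune genes. AttD rose by log2 4.00 ± 0.64 (SE, 12 and 12 arrays; 16-fold; adjusted p = 0.00202; higher in 11 of 12 lines) and Def by 3.10 ± 0.58 (adjusted p = 0.00532, 12 of 12 lines). Hayan, a serine protease of the melanization cascade, rose by log2 2.31 ± 0.45 (adjusted p = 0.00689, 12 of 12 lines), pirk by 2.20 ± 0.40 and Pu by 1.79 ± 0.31 (each 12 of 12 lines). On the falling side alpha-Est2, a carboxylesterase, fell by 1.82 ± 0.31 on the log2 scale (11 of 12 lines) and Miox fell by 1.53 ± 0.29 (11 of 12 lines). The gene apolpp, for the precursor of the main lipid carrier of the hemolymph, changed by log2 -0.65 (adjusted p = 0.00367).

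Of the 6 antimicrobial peptide genes 2 rose at 4 weeks (5 when adjusted over the list alone), and the list held with both forms of camera (adjusted p = 1.52e-10, and adjusted p = 0.016 with an estimated correlation). CecB changed by log2 2.66 ± 0.68 (adjusted p = 0.0702), and passed without line 6 (adjusted p = 0.0274), line 14 (0.00583) or the line 14 young sham array alone (0.00132). Of 10 melanization genes 1 rose (6 when adjusted over the list alone), and of 8 PGRP and GNBP genes 1 (4 rose and 1 fell when adjusted over the list alone). Of 14 Imd pathway genes 2 rose (4 rose and 1 fell when adjusted over the list alone). Camera gave adjusted p = 1.54e-06, 0.00091 and 0.0109 for these 3 lists, and adjusted p = 0.241 for each with an estimated correlation. Of 14 Toll pathway genes 1 rose (1 when adjusted over the list alone), with camera adjusted p = 0.0225 and adjusted p = 0.326 with an estimated correlation. This was spirit, a serine protease upstream of Toll (log2 2.23 ± 0.50), which missed the threshold without line 1, 3, 4, 8, 13, 17, 18 or 19 (adjusted p = 0.0544 to 0.117). Of 22 lipid genes 1 fell (5 when adjusted over the list alone; camera adjusted p = 0.00217, and adjusted p = 0.438 with an estimated correlation).

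In all, 27 probe sets rose and 14 fell with infection at 4 weeks, and camera called 9 of 32 lists, of which 1 held with an estimated correlation. The total was 26, 16, 27, 27, 17 and 27 without lines 12, 4, 13, 17, 19 and 20, and 49 rose and 18 fell without the line 14 young sham array. It was 61 with array set as an added block (31 rose and 30 fell), 8 in array set 1 alone (5 and 3), and 5 without line as a block (4 and 1). Of the 31 probe sets that rose at 1 week and the 27 that rose at 4 weeks, 16 were shared, where chance gives 0.0958, and of the 14 and 14 that fell 5 were shared, where chance gives 0.0224. No probe set rose at one age and fell at the other.

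**Figure D1:**
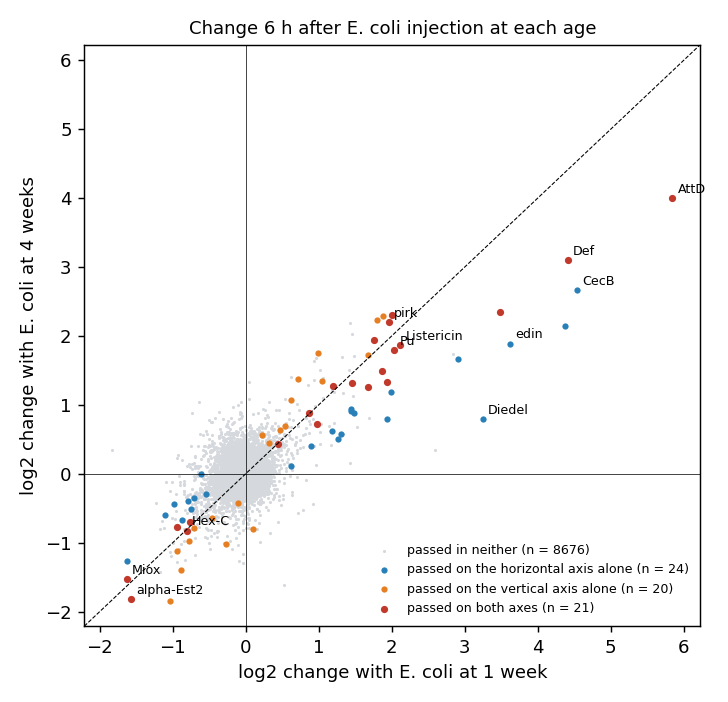
Log2 fold change with infection at 1 week (horizontal axis) against 4 weeks (vertical axis), 1 point for each kept probe set, coloured by the comparison in which it passed adjusted p under 0.05. AttD lies at a fitted 5.85 and 4.00, and 21 probe sets passed at both ages.

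Whether the response to infection changed with age was tested directly. No single gene passed this test (0 probe sets by limma, 115 at an unadjusted p under 0.05), and none did without the line 14 young sham array (116 at an unadjusted p under 0.05). The change with infection at 4 weeks minus that at 1 week was log2 -1.87 for CecB, -1.85 for AttD and -1.31 for Def (adjusted p = 0.999 for each). Of the 6 antimicrobial peptides, 0 passed when adjusted over the list alone. Camera called the list downward (adjusted p = 5.69e-07), with adjusted p = 0.111 with an estimated correlation; without the line 14 young sham array these were 1.47e-15 and 0.00019, and 4 of the 6 genes passed when adjusted over the list alone.

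The mean over the 6 peptides gives the same contrast line by line. Infection raised it by log2 2.60 ± 1.17 at 1 week (SD, n = 10 lines; 9 of 10 above 0) and by 1.67 ± 0.62 at 4 weeks (10 of 10). The difference was -0.93 ± 1.17, with 9 of 10 lines below 0 (two-sided sign-flip permutation p = 0.0371; adjusted p = 0.0742 over the 4 tests of a single value per line, so that it failed the correction). It missed 0.05 without line 1, 3, 6, 8, 12, 13, 17 or 19 (permutation p = 0.0586 to 0.0742). Without the line 14 young sham array it was -1.25 ± 0.58 in 9 of 9 lines (exact sign-flip permutation p = 0.00391, the smallest that 9 lines can give; adjusted p = 0.00781 over the 4 tests). In the 4 lines with all their arrays in array set 1 it was -1.43 (exact permutation p = 0.125, the smallest that 4 lines can give). Without line as a pairing the permutation p was 0.0419. A high sham level leaves less room for a rise: DptB and Drs had means of 13.91 and 14.59 in 4-week sham arrays, and Mtk stood higher, on a scale that ends at 15.5, while AttD had a mean of 3.35 in 1-week sham arrays. CecB, AttD and Def had the largest differences between ages. Their 4-week sham means were 8.17, 6.54 and 10.04. Their 4-week infected means were 10.83, 10.54 and 13.14, with highest values of 12.22, 13.39 and 14.24. For CecB and AttD these means argue against the top of the scale as the whole cause. Def came nearer to the top, so a limit there is not excluded for it. The difference in the peptide mean also uses the same sham arrays as the comparison of sham levels that follows, so the 2 are not independent.

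The same peptides were compared between ages in sham flies, without bacteria. The mean over the 6 genes was higher at 4 weeks than at 1 week by log2 1.63 ± 1.27 (SD, n = 12 lines, 11 of 12 above 0; exact sign-flip permutation p = 0.00293; adjusted p = 0.0117 over the 4 tests). Without the line 14 young sham array the rise was 1.91 ± 0.87 in 11 of 11 lines (exact permutation p = 0.000977, the smallest that 11 lines can give). In the 6 lines with both sham arrays in array set 1 it was 2.24, in 6 of 6 lines (exact permutation p = 0.0313, the smallest that 6 lines can give). Without line as a pairing the permutation p for all lines was 0.00053.

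Lines in which infection raised the peptides more at 1 week were not shown to be those in which it raised them more at 4 weeks. Pearson's r was 0.269 (permutation p = 0.367) and Spearman's rho 0.333 (permutation p = 0.351) over 10 lines. The adjusted p for r over the 4 tests was 0.489. Leaving out lines 14 and 6, the farthest from the median at 1 week, gave r = 0.27. Without the line 14 young sham array r was 0.623 (exact permutation p = 0.073) and rho 0.45 (exact permutation p = 0.23) over 9 lines, and r = 0.501 without lines 6 and 4. Array set 1 held all 4 arrays of 4 lines, too few for a correlation.

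**Figure D2:**
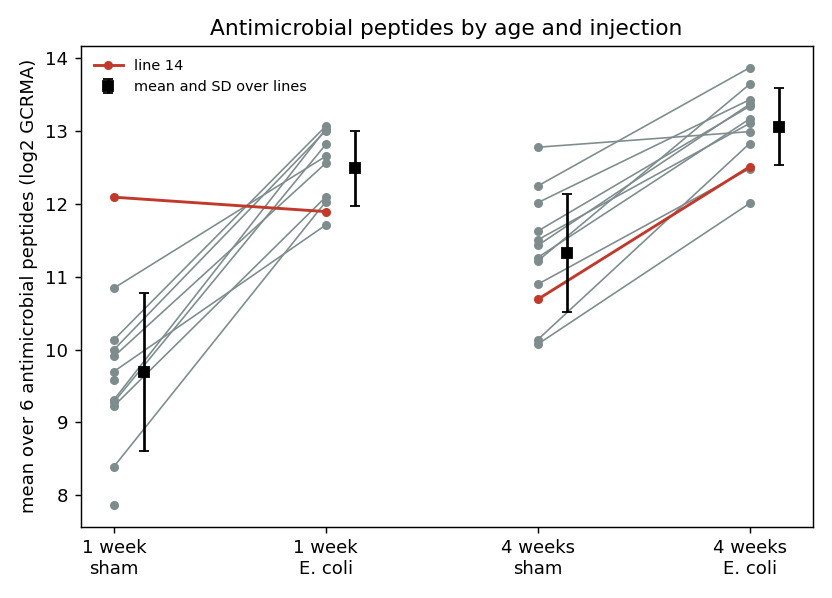
Mean log2 signal over the 6 antimicrobial peptide genes (vertical axis) in the 4 groups of age and injection (horizontal axis), with 1 joined set of points for each line and line 14 in red; squares with bars are the mean and SD over lines. In line 14 the 1-week sham array stands at 12.09 and the 1-week infected array at 11.90, while in the other 9 lines with both arrays infection raised the mean.

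Age in sham-injected flies asked which genes differ between young and old flies after a sterile wound. The calcium-binding protein gene Scp1 (Entrez Gene 3355102) had the largest fall, at log2 -3.04 ± 0.24 (SE, 12 and 12 arrays; adjusted p = 9.92e-11; lower in 12 of 12 lines). Other falls were the small heat shock gene CG7409 (log2 -1.97 ± 0.21), Hsc70-1 (-1.37 ± 0.21), the antennal protein gene a10 (-1.63 ± 0.34, 12 of 12 lines), and the neuropeptide-like precursor Nplp3 (-1.49 ± 0.28). Of 20 muscle genes 2 fell (1 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.0584), the actin gene Act79B (-1.26 ± 0.17, 12 of 12 lines) and the troponin C gene TpnC41C (-0.80 ± 0.17, 12 of 12 lines). Hsc70-1 had 2 further probe sets, which changed by -1.52 (adjusted p = 1.18e-05) and 0.30 (adjusted p = 0.649). Rises included CecB (log2 3.25 ± 0.68, adjusted p = 0.0101, 11 of 12 lines) and AttD (a fitted 3.19 ± 0.64 from a 1-week mean below the filter value, so its size is not exact; adjusted p = 0.0074, 11 of 12 lines), as well as Peritrophin-15b (1.87 ± 0.31) and the metallothionein gene MtnD (1.39 ± 0.26).

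Of the 6 antimicrobial peptide genes 4 rose with age in sham flies (6 when adjusted over the list alone; camera adjusted p = 2.01e-09, and adjusted p = 0.0286 with an estimated correlation). DptB rose by log2 0.63 ± 0.13 (adjusted p = 0.0566 without line 1 and 0.0529 without line 18) and Mtk by 0.55 ± 0.14 (adjusted p = 0.0548 to 0.142 without line 1, 3, 4, 6, 8, 12, 13, 18, 19 or 20). Def changed by 1.97 (adjusted p = 0.0888) and Drs by 0.18 (adjusted p = 0.143), and without line 14 both passed (adjusted p = 0.00252 and 0.0155). Of 21 glutathione transferases 1 rose (2 when adjusted over the list alone; camera adjusted p = 0.000113, and adjusted p = 0.294 with an estimated correlation). It was GstO3 (0.97 ± 0.22), with adjusted p = 0.0633 to 0.0972 without line 3, 4 or 8. Of 29 gut digestive enzymes 2 rose (2 when adjusted over the list alone; camera adjusted p = 0.000456, and adjusted p = 0.669 with an estimated correlation). Among them was Jon65Aiii, a serine protease (0.43 ± 0.10), with adjusted p = 0.055 to 0.0996 without line 3, 4, 8, 12, 18 or 20. No cytochrome P450 gene of 53 passed (0 when adjusted over the list alone), with camera upward at adjusted p = 0.000453 and adjusted p = 0.669 with an estimated correlation.

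Across all probe sets, 60 rose and 27 fell with age in sham flies, and camera called 9 of 32 lists, of which 1 held with an estimated correlation. With the line 14 young sham array left out, 529 rose and 802 fell. The total was 1231 without line 14 and 56, 46, 53, 44, 44, 47 and 48 without lines 1, 3, 4, 8, 12, 13 and 18. With array set as an added block it was 95 (66 rose and 29 fell), in array set 1 alone 697 (325 and 372), without line as a block 18 (8 and 10), and with the 3' minus 5' signal as a covariate 166 (102 and 64). In array set 1 the line 14 young sham array stands alone for its line, so it does not move the contrasts of that fit. Falls outnumbered rises with array weights (870 rose and 1883 fell) and in the 10 lines with all 4 arrays (13 and 18).

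In infected flies no antimicrobial peptide gene of 6 passed the test of age (0 when adjusted over the list alone). The mean over the 6 genes was still higher at 4 weeks than at 1 week in every line with both infected arrays. The difference was smallest in line 3 (log2 12.82 at 1 week and 12.83 at 4 weeks) and largest in line 1 (12.03 and 13.11). No permutation test of it was run. The largest fall was again that of Scp1 (log2 -2.82 ± 0.26, 12 and 10 arrays; adjusted p = 4.4e-09; 10 of 10 lines). Falls also included CG7409 (-2.09 ± 0.22, 10 of 10 lines), Nplp3 (-1.72 ± 0.30, 9 of 10 lines) and Hsc70-1 (-1.17 ± 0.22, 10 of 10 lines). Act79B fell by 0.76 ± 0.18 (10 of 10 lines) and retinin, a protein of the corneal lens, fell by 1.24 ± 0.26 (9 of 10 lines). Rises included CG12506 (2.87 ± 0.69, 9 of 10 lines), the cuticle protein gene Cpr66D (2.01 ± 0.47, 10 of 10 lines) and hdly (1.82 ± 0.36, 9 of 10 lines). Diedel, which rose with infection at 1 week, was lower in old than in young infected flies (-2.33 ± 0.64, adjusted p = 0.0393, 8 of 10 lines).

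Of 53 cytochrome P450 genes 3 rose (11 when adjusted over the list alone; camera adjusted p = 7.85e-08, and adjusted p = 0.408 with an estimated correlation), among them Cyp6a18 at log2 1.23 ± 0.30. Of 29 gut digestive enzymes 3 rose (9 when adjusted over the list alone; camera adjusted p = 1.28e-05, and adjusted p = 0.408 with an estimated correlation), among them the proteases Jon65Aiv (0.67 ± 0.14) and Jon65Aiii (0.51 ± 0.11). Of 9 iron binding genes 2 rose (2 when adjusted over the list alone; camera adjusted p = 0.00165, and adjusted p = 0.408 with an estimated correlation), the ferritin genes Fer2LCH (0.38 ± 0.10) and Fer1HCH (0.28 ± 0.08). Of 22 lipid genes 1 rose (6 when adjusted over the list alone; camera adjusted p = 0.000758, and adjusted p = 0.408 with an estimated correlation), Fatp, a fatty acid transport protein, by 0.68 ± 0.18.

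Many of these calls lay near the threshold. Of the genes named for infected flies, Scp1, CG7409, Nplp3, Hsc70-1 and hdly passed whichever line was left out. Without line 8 all the others missed the threshold (adjusted p = 0.0543 to 0.108), and without line 1 all the others but retinin did (0.0501 to 0.108). The changes themselves moved little without line 8, as in Act79B (log2 -0.80), Jon65Aiv (0.68) and Diedel (-2.28), while Diedel stood at -1.78 without line 3. Without line 3 this was so for CG12506, Cyp6a18, Fer2LCH, Fer1HCH, Fatp and Diedel (0.0607 to 0.107), without line 4 for CG12506, Fer2LCH, Fer1HCH, Fatp and Diedel (0.0751 to 0.0899). This also held without line 6 for Fer2LCH and Fer1HCH, without line 12 for Fatp and Diedel, without line 13 for Diedel, without line 18 for Fatp and Fer1HCH, without line 19 for Cyp6a18, Fer1HCH and Diedel, and without line 20 for Fatp and Fer1HCH (0.051 to 0.0715).

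Camera called 8 of 32 lists, of which 0 held with an estimated correlation. In all, 171 probe sets rose and 85 fell with age in infected flies, and 396 rose and 351 fell without the line 14 young sham array. The total was 24, 47, 51, 13, 418, 514, 124 and 162 without lines 1, 3, 4, 8, 13, 14, 18 and 20, and without line 19, 121 rose and 35 fell. It was 307 with array set as an added block (171 rose and 136 fell), 3 in array set 1 alone (0 and 3), 9 without line as a block (2 and 7) and 389 with the 3' minus 5' signal as a covariate (242 and 147), and with array weights 1454 rose and 1593 fell. Of the 60 probe sets that rose in sham and the 171 that rose in infected flies 31 were shared (1.17 by chance), and of the 27 and 85 that fell 14 were shared (0.263 by chance), with none in opposite directions.

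**Figure D3:**
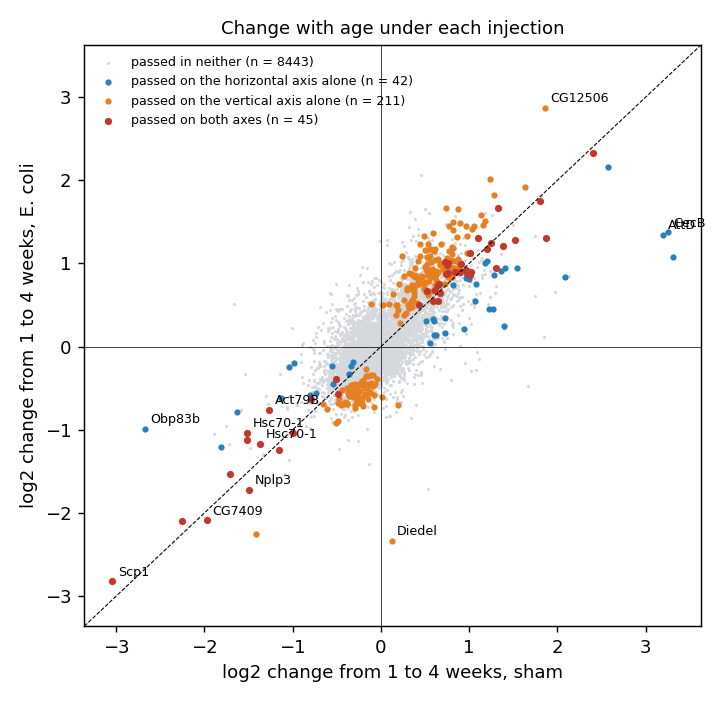
Log2 fold change with age in sham-injected flies (horizontal axis) against infected flies (vertical axis), 1 point for each kept probe set, coloured by the comparison in which it passed adjusted p under 0.05. Scp1 lies lowest on both axes, at -3.04 and -2.82, and 45 probe sets passed under both injections.

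Line reached more probe sets than age or injection. Of 8741 probe sets, 4156 (47.6%) differed between lines (limma moderated F-test). NaPi-III, a phosphate transporter gene, had the highest F (877), with a mean log2 signal of 11.59 in line 6 and near the floor in line 19. The small heat shock gene Hsp26 stood at 2.23 in line 6 and at 13.78 in line 19, and Smurf, a ubiquitin ligase gene, at 3.10 in line 3 and 10.52 in line 6. Of 29 gut digestive enzymes 29 differed between lines (29 when adjusted over the list alone), and of 53 cytochrome P450 genes 45 (45 when adjusted over the list alone). Of 21 glutathione transferases 17 differed (18 when adjusted over the list alone) and of 20 muscle genes 15 (15 when adjusted over the list alone). Of 30 cytosolic ribosomal protein genes 1 differed (0 when adjusted over the list alone), of 26 proteasome genes 0 (0 when adjusted over the list alone), and of the 6 antimicrobial peptide genes 2 (2 when adjusted over the list alone). Probe sequences were not compared with the lines' genomes here, so a signal at the floor in 1 line is not shown to be absence of the transcript.

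The F-tests of line by age and line by infection had at most 1 pool per line, age and injection. For line by age the injections of a line served as replicates, and for line by infection its ages. Any other effect shared by a line's pools at an age therefore cannot be told apart from line by age. The change with age differed between lines for 30 probe sets (limma moderated F-test, 1436 at an unadjusted p under 0.05), led by Nplp3 (F = 12.2, adjusted p = 0.00375). Others were Cyp6a17, a cytochrome P450 gene (F = 10.1, adjusted p = 0.00383), Tango10 (F = 10.5, adjusted p = 0.00383) and La (F = 9.36, adjusted p = 0.00642). The count was 19, 12, 12, 18, 304, 11, 9, 16 and 49 without lines 1, 3, 8, 13, 14, 17, 18, 19 and 20, 46 without the line 14 young sham array, and 19 with array set as an added block. It was 16 in the 10 lines with all 4 arrays, 176 with array weights and 487 without a filter. The change with infection differed between lines for 1 probe set, that of Cp15, an eggshell protein gene (F = 15.4, adjusted p = 0.000417), with 611 at an unadjusted p under 0.05. This count was 2 without line 3, 41 without line 17, 0 without line 18 and 30 without the line 14 young sham array. It was 372 without the 4 arrays nearest another line and 194 without a filter.

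The spread of the lines around their mean was compared between ages in sham arrays. The median over 8741 probe sets of the log2 ratio of the SD over 12 lines at 4 weeks to that at 1 week was 0.04 (permutation of ages within lines, p = 0.627; adjusted p = 0.627 over the 4 tests). In all, 53.7% of probe sets had the larger SD at 4 weeks. Without the line 14 young sham array the ratio was 0.02 (permutation p = 0.911).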

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

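The tests of the line pattern, of array sets, of hemocyte markers and of the gaps over 9 lines were chosen only after the results were seen, and the test of RNA integrity for the peptides was set before its result was seen.

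The array labelled line 14, 1 week, sham carries the expression pattern of line 4. On 131 probe sets that separate the lines it lies at 1.09 of the way from line 14 to line 4, while the other line 14 arrays lie at 0.371 (4 weeks, sham), 0.113 and 0.207, and this is consistent with a mislabelled or exchanged sample. Low RNA integrity is argued against as the whole cause: its 3' minus 5' signal is high (10.7), but of 17 other arrays over 7 only 1 lies nearest another line; array set is argued against too, since its mean correlation with line 4 arrays of its own set minus that with line 4 arrays of other sets is -0.068. Its nearest array is that labelled line 4, 4 weeks, infected (r = 0.947), with CecB at log2 12.28 and Scp1 at 12.27 (12.22 and 12.44 in that array). It lies at 1.65 of the way from sham to infected on 27 genes and at 1.41 of the way from 1 to 4 weeks on 83 genes (1.46 and 1.70 in that array). Infection positions are read within the array's labelled age and age positions within its labelled injection. The positions of the 2 arrays are therefore not on the same axes and do not show a match. All line 4 arrays lie nearest their own line, so no partner of an exchange was found here. A second pool of line 4 stays open, which pool the array holds was not settled, and no biological explanation was tested. Among the 42 arrays nearest their own line the highest position toward another line was 0.869. It was that of the line 14 array of 4 weeks, sham, toward line 17 (70.6% of 691 probe sets nearer line 17). Outside those 42, the 4-week infected array labelled line 17 lies at 0.815 toward line 18, and whether it was exchanged was not settled.

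Antimicrobial peptides stood higher in old than in young sham flies, by a mean log2 change of 1.63. With the 3' minus 5' signal as a covariate the change was 1.62 ± 0.30 (SE), and with array set as a block 1.58 ± 0.30, which argues against RNA integrity or labelling and against array set as the whole cause. More hemocytes in the old pools, if these were the main source of the peptides, would raise their markers about as much. The median change of 7 markers was 0.0232 (SD 0.24). Sr-CIV changed by 0.46, NimC1 by 0.33, crq by 0.21, Pxn by 0.02, vkg by -0.07, Hml by -0.10 and Col4a1 by -0.18. Sr-CIV and NimC1 had means of 3.21 and 3.71, below the filter value of 4, so their changes are not exact. Which cells made the peptides was not tested, so a part for hemocytes is not excluded. A hypothesis is that old flies may hold a higher level of immune gene expression before bacteria enter, or may respond more to the wound itself. Uninjected flies were not analysed here, so these remain open.

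Some lines stood far from the others, measured by the gap to the nearest other line as a share of the whole range. In all, 47 groups of values over the same lines were tested, and 8 passed the critical value. Chance gives about 1 in 20 for independent groups of normally distributed values. These groups share lines and arrays, and AttD holds a value at the floor, so an excess over chance is not shown. For the mean over 6 antimicrobial peptides, line 14 was lowest for the change with infection at 1 week (share 0.513) and highest for the difference between ages (0.516), and line 6 was lowest for the change at 4 weeks (0.484). Both line 14 values rest on its 1-week sham array, which carries the line 4 pattern; over the other 9 lines the 3 shares were 0.106, 0.391 and 0.484, and none of these passed the critical value. Among levels in 1-week infected flies, the share was 0.677 for Diedel in line 6, 0.51 for Miox in line 19, 0.654 for CG12506 in line 12, 0.656 for Cpr66D in line 4 and 0.469 for CG9297 in line 3.

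The mean over the 6 antimicrobial peptides, of which 3 lay near the top of the scale in sham flies, gave a change with infection at 4 weeks minus that at 1 week of log2 -0.93, which failed the correction (permutation p = 0.0371, adjusted p = 0.0742 over 4 tests) and missed 0.05 in 8 of the 10 fits that left out 1 line. For this difference camera gave an adjusted p of 5.69e-07 for antimicrobial peptides (lower at 4 weeks; adjusted p = 0.111 with an estimated correlation) and 0.0421 for bomanins and other immune-induced peptides (lower; adjusted p = 0.901 with an estimated correlation). Lists with a higher change at 4 weeks were tricarboxylic acid cycle genes (0.0164; adjusted p = 0.682 with an estimated correlation), cytochrome P450 genes (0.00308), lipid storage and metabolism genes (0.0164), iron binding genes (0.0421) and muscle genes (0.0421), the last 4 with adjusted p = 0.901 with an estimated correlation. No gene of these 7 lists passed on its own (limma; 115 of all probe sets had an unadjusted p under 0.05). Without the array labelled line 14, 1 week, sham the camera adjusted p was 0.145 for tricarboxylic acid cycle, 0.178 for cytochrome P450, 0.17 for lipid, 0.278 for iron binding and 0.237 for muscle genes. The peptide difference kept its sign and was larger without that array, at log2 -1.25 in 9 of 9 lines (sign-flip permutation p = 0.00391, adjusted p = 0.00781 over 4 tests). Of the 6 peptides, CecB, AttD and Def differed most between ages and were not among the 3 near the top of the scale in sham flies. In 4-week infected flies Def averaged log2 13.14, so a limit at the top is not excluded for it.

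In the tests of line by age and line by infection, a line's pools under the other factor served as its replicates. The change with age differed between lines for 30 probe sets, and the change with infection for 1, the eggshell gene Cp15. Leaving out 1 line at a time, these counts ran from 9 (without line 18) to 304 (line 14) and from 0 (line 18; limma, with 611 at an unadjusted p under 0.05 over all lines) to 41 (line 17), and without the array labelled line 14, 1 week, sham they were 46 and 30. With residuals shuffled over arrays, 6 of 100 runs, the real one included, gave as many as the count of 1, so chance is not excluded for it.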

How the results depend on the processing

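Fits without the array labelled line 14, 1 week, sham, without the 4 arrays nearest another line, with the 3' minus 5' signal as a covariate, and with gene-by-gene array weights were chosen only after the results were seen. In what follows, counts of probe sets are given for infection at 1 week, infection at 4 weeks, age in sham and age in infected flies, in that order; all of these were 45, 41, 87 and 256 in the planned fit. The interaction count was 0 by limma in all settings run (115 at an unadjusted p under 0.05 in the planned fit). Where no reason is given, the cause was not tested.

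Without the array labelled line 14, 1 week, sham the counts were 87, 67, 1331 and 747, and they held 44, 41, 87 and 256 of the probe sets of the planned fit; line by age went to 46 and line by infection to 30. Without the 4 arrays nearest another line infection at 1 week gave 99, age in sham flies 1781 and age in infected flies 939, and line by infection 372. With the covariate age in sham flies gave 166, age in infected flies 389 and line by infection 2. Array weights gave 335 (157 rose and 178 fell), 113 (89 and 24), 2753 (870 and 1883) and 3047 (1454 and 1593), with line at 7848 and line by age at 176, and gene-by-gene weights 286 (135 and 151), 125 (90 and 35), 2671 (861 and 1810) and 2892 (1380 and 1512), with line at 7582 and line by age at 137. Without a filter infection at 4 weeks gave 21, age in sham flies 42 and age in infected flies 43, with line by age at 487 and line by infection at 194. Quantile normalization gave 137 for age in sham flies and 2 for line by infection. Array set 1 alone, which holds fewer arrays, gave 8 for infection at 4 weeks (5 rose and 3 fell), 697 for age in sham (325 and 372) and 3 for age in infected flies (0 and 3), and at 1 week 35 rose and 1 fell with infection. Fewer arrays do not account for the higher count of 697. Of line 14, array set 1 holds only the 1-week sham array. With line as a block, an array that stands alone for its line does not move the contrasts. In effect the fit of array set 1 therefore leaves that array out, as does the fit that gave 1331. The 10 lines with all 4 arrays gave 23 (14 and 9) for infection at 4 weeks, 31 (13 and 18) for age in sham and 57 (40 and 17) for age in infected flies. In these lines 28 rose and 27 fell with infection at 1 week, with line by age at 16 and line by infection at 0 (limma, 495 at an unadjusted p under 0.05). Array set as an added block gave 19 for line by age. Without line as a block the counts were 24 (21 rose and 3 fell), 5 (4 and 1), 18 (8 and 10) and 9 (2 and 7).

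Leaving out 1 line at a time gave 32 (without line 8) to 85 (line 14) for infection at 1 week, 16 (line 4) to 47 (line 14) for infection at 4 weeks, 44 (lines 8 and 12) to 1231 (line 14) for age in sham flies, 13 (line 8) to 514 (line 14) for age in infected flies, 3128 (line 6) to 5017 (line 14) for line, 9 (line 18) to 304 (line 14) for line by age, and 0 (line 18) to 41 (line 17) for line by infection. The peptide difference between ages ran from -1.25 (line 14) to -0.80 (line 1), and lost a permutation p under 0.05 without 8 of the 10 lines; the peptide rise in sham flies ran from 1.47 (line 18) to 1.91 (line 14), r across lines from 0.134 (line 6) to 0.623 (line 14), and the spread from 0.016 (line 14) to 0.107 (line 17).

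In infected arrays of the lines with all 4 arrays the spread was -0.0466, against 0.0439 in sham arrays (permutation p = 0.799 and 0.627). The median change of DNA replication and cell cycle genes with infection at 1 week was -0.0203 without the array labelled line 14, 1 week, sham, against 0.0946. Camera called 46 shifts of lists with the preset correlation and 5 with an estimated correlation. Over the named genes and all alternatives, 10275 values kept direction and side of the threshold, 664 lost the threshold, 147 gained it and 0 reversed. Values at or near the floor of 2.16 and near the top of the scale limit what changes the arrays can show.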

Other observations

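The test of RNA integrity for the age-related falls was set before its result was seen. The test of muscle and all tests against other splits or shuffles of the arrays were chosen only after the results were seen, as were the values without the array labelled line 14, 1 week, sham.

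Without the array labelled line 14, 1 week, sham 9 of 17 DNA replication and cell cycle genes fell with age in sham flies (14 when adjusted over the list alone), among them the origin recognition genes Orc2 (log2 -0.68 ± 0.16, SE, lower in 11 of 11 lines) and Orc5 (-0.57 ± 0.13, 11 of 11 lines) and fzy, an activator of mitotic exit (-0.62 ± 0.17, 11 of 11 lines). With all arrays 0 of 17 passed (0 when adjusted over the list alone), and camera gave adjusted p = 0.000872, with adjusted p = 0.696 with an estimated correlation. Of 17 female germline genes 4 fell without that array (10 when adjusted over the list alone), among them spn-E (-0.45 ± 0.14); with all arrays 0 did (0 when adjusted over the list alone; camera adjusted p = 0.00614, and adjusted p = 0.696 with an estimated correlation).

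In the same fit without that array, of 53 cytochrome P450 genes 8 rose and 2 fell with age in sham flies (8 and 2 when adjusted over the list alone), with Cyp4p3 at log2 1.41 ± 0.26 (11 of 11 lines), and of 21 glutathione transferases 7 rose (8 when adjusted over the list alone), with GstD2 at 1.55 ± 0.38 (9 of 11 lines). Camera gave adjusted p = 3.37e-05 and 0.000159 for these lists, and adjusted p = 0.429 and 0.381 with an estimated correlation.

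The genes Scp1, Act79B and SERCA, chosen after their values were seen, fell with age in sham flies, with a median log2 change of -1.26. A lower share of muscle in the old pools would lower muscle genes alike, but the median over the 19 other muscle genes was -0.18 (SD 0.44), and 4 of these fell below the weakest of the 3, which argues against it as the whole cause. With the 3' minus 5' signal as a covariate the median of the 3 was -1.27, which argues against RNA integrity or labelling. The 3 SERCA probe sets differed, at log2 -2.25, -0.79 (the one used here) and -0.11 (adjusted p = 0.761), so a change in transcript forms stays open, as does age itself, untested.

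Each of the 4 contrasts of infection or age was compared with 100 splits in which the labels were exchanged within random lines, the real split included. For infection at 1 week 2 of 100 splits called as many probe sets (45 in the real one, at most 80 in the others, where line 14 alone was exchanged), for infection at 4 weeks 1 (41, at most 0 in the others), for age in sham flies 2 (87, at most 1311) and for age in infected flies 1 (256, at most 200, with lines 3 and 13 exchanged). The share of splits with as many calls was under 0.05 for each of these 4 counts. The split with 1311 calls, several times the real count, exchanged every line but 1 and 14, the mirror of exchanging those alone. Without the array labelled line 14, 1 week, sham the numbers were 1 (87 calls, at most 34), 1 (67, at most 29), 1 (1331, at most 629) and 2 of 100 splits (747, at most 894, with lines 3 and 13 exchanged). No other split then reached the real count for infection at 1 week or age in sham flies. Without that array line 14 had no pair to exchange in these contrasts, so the splits with 80 and 1311 calls could not be drawn again. Their absence does not show that the excess went with that array. For the split of lines 3 and 13 a structure of the arrays stays open, and its source was not tested. For the interaction no labels were exchanged: residuals of a model with age, injection and line were shuffled over arrays. The real interaction count was 0 (limma, 115 at an unadjusted p under 0.05), so every run gives at least as many by construction (100 of 100, at most 0 in the others), and the comparison decides nothing.

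With lines exchanged among the arrays of each group, 1 of 100 splits gave as many probe sets for line (4156, at most 407). For line by age and line by infection, residuals of a model with group and line were shuffled over arrays instead. As many probe sets came from 2 of 100 runs for line by age (30, at most 178) and 6 for line by infection (1, at most 41). Chance is therefore not excluded for the last, a count of 1 with all arrays. For line by age the run with 178 calls gave several times the real count. A structure of the arrays stays open there, and its source was not tested. The numbers of lists called by camera with the preset correlation were matched by 16 of 100 splits for infection at 1 week (13 lists, at most 16), 24 for infection at 4 weeks (9, at most 13), 44 for age in sham flies (9, at most 18), 55 for age in infected flies (8, at most 15) and 45 of 100 runs with shuffled residuals for the interaction (7, at most 17), so chance is not excluded for these 5 numbers.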
